A study of Arabidopsis thaliana with 6 samples.

How the data were processed

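Total RNA from Arabidopsis cotyledons was hybridised to Affymetrix ATH1 arrays, which carry 22810 probe sets, with 1 array per sample and 2 arrays in each of 3 groups (mock, early, late). The values are linear intensities per probe set as deposited by the authors. The submitters' processing notes name MAS5, without a version or a role. The values have 1 decimal, are never negative, include between 1 and 20 exact zeros per array, and have a trimmed mean (2 percent left out at each end) of 100.01 on each array, so each array had been scaled to one common level. Detection calls and scanner files were not analysed here. MAS5-type values of dim probe sets are noisy, and a scaling to a common mean removes any difference in total RNA between the groups.

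The 64 control probe sets were left out of the tests. The intensities were used as deposited and converted to log2(value + 7.2), where 7.2 is the 25th percentile of all values. This pseudocount makes the fold change of dim genes appear smaller than it is. Tested were the 13647 probe sets whose mean log2 value lay above the 40th percentile (4.717) of the non-control probe sets. All arrays entered one limma fit (limma 3.58.1, lmFit and eBayes with a mean-variance trend, R 4.3.3), with 3 residual degrees of freedom and 7.01 prior ones. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicates come from independent experiments per the labels' protocols, but the labels do not say that a replicate number marks an experiment, so the fit had no replicate block. The mock time points are not given in the sources used here. No sample was left out and no column was unmapped.

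Gene names came from the platform annotation supplied with the values, updated through gene identifiers to the RefSeq annotation of TAIR10.1, which was used for names only. It gave 1 gene for 13513 probe sets, of which 13436 matched RefSeq, several genes for 503 and none for 8730. A probe set without a name here is unnamed, not without a gene. Many well-studied genes had no named probe set. Of 12 genes to be given whatever their p, PDF1.2 was the one with a named probe set, so PR1, PR2, PR5, DMR6, IOS1, LURP1, PAD3, ICS1, FMO1, RBCS1A and VSP2 are not analysed here. Where a gene had several probe sets, the one with the highest mean was used.

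The design, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule took, among called probe sets of 1 gene whose arrays did not overlap between the groups, the 6 largest rises and 6 largest falls against mock at each stage and the 4 and 4 between stages. It also took the 2 largest changes of each list with called members, and the member with the smallest p of a list with none. Of 26 preset lists (450 genes), 57 genes had a named probe set and 48 were tested. No member could be tested for 10 lists, which cover jasmonate, receptor-like kinases, mildew susceptibility, camalexin, oxidative stress, nitrogen, cell cycle, root, shoot apex and seed, and vascular tissue. The minimum of tested members for a list test was first 5 and was lowered to 3 after the members' changes had been seen, so it is not among the choices fixed in advance. The 8 preset lists with 3 or more tested members were tested with camera (correlation preset to 0.01, and again estimated) and fry. Another 27 lists were written from the annotation before any group comparison was run. They were tested as a family of their own. The list of mitochondrion-encoded genes was corrected, to leave out plastid genes, after its counts had been seen. The count of calls in opposite directions at the stages was added after seeing the data. Further lists for the closing tests were written after the leading genes were known, and 1 gene that encodes an elongation factor subunit was taken out of one of them after its value was seen.

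The fit was tested on simulated data, with 200 of 13647 probe sets changed in each of 20 draws per comparison. These data used the real means, the moderated spreads of the fit and normal noise drawn independently for each probe set. The recovery on real arrays, where noise can be shared between probe sets, may be lower. Of changes of 2 on the log2 scale, 99.9 percent were recovered for early against mock and 100 percent for the other comparisons. Of changes of 1, 92.2 percent were recovered for early against mock, 90.9 percent for late against mock and 91.8 percent for late against early. The share of false calls was 7.57, 7.51 and 7.39 percent, above the nominal 5 percent. Alternatives were quantile normalization, median centring, other pseudocounts and filters, a replicate block, other moderation, array weights, fits of only the compared groups, other thresholds and leaving out each array in turn. When an array is left out, the lone array of its group is assumed to vary like the others. The overlap of the comparisons was set against 100 simulations of unchanged groups that share the mock arrays.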

Results

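Transcript levels were measured in cotyledons of Arabidopsis thaliana ecotype Wassilewskija after inoculation with water (mock) or with Hyaloperonospora arabidopsidis, the oomycete that causes downy mildew of this plant. The interaction was compatible, meaning that the pathogen can grow in the host. RNA from 8 h and 24 h after inoculation was pooled as the early sample, and RNA from 4 d and 6 d was pooled as the late sample. The mock samples were also pools, but the labels used here do not give their collection times, so a change against mock can include the time of collection as well as the infection. Each group had 2 arrays from 2 independent experiments, and this number of arrays limits the precision of every value. Intensities of 22810 probe sets were scaled by the authors to a common trimmed mean of 100.01 on each of the 6 arrays, and the array medians lay between 33.5 and 38.4. Over the tested probe sets, the correlation between the 2 arrays of a group was 0.98 for mock, 0.99 for early and 0.98 for late.

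The early comparison asked which host transcripts differed from mock at the start of the interaction. Heat shock genes showed the 4 largest falls among named genes at the pseudocount of 7.2. HSP17.6C (AT1G53540), a small heat shock protein, went from an intensity of 137.8 ± 144 in mock to 3.6 ± 0.707 (SD, n = 2) in the early group and fell by 3.26 ± 0.60 (SE) on the log2 scale. Its early values lay below that pseudocount, and with a pseudocount 4 times larger the change was -2.03 and did not pass (limma adjusted p = 0.0519). On the mock arrays it was at 239.4 and 36.1, and without mock replicate 1 the change was -2.01. The log2 change was -2.90 ± 0.43 for the small heat shock protein gene AT2G29500, -2.87 ± 0.42 for the co-chaperone gene ROF2 (AT5G48570) and -2.80 ± 0.42 for the small heat shock protein gene AT5G37670. The mock arrays stood apart for these genes too. They were at 356 and 102.2 for AT2G29500, 263.6 and 72.5 for ROF2, and 230.4 and 80.1 for AT5G37670. Leaving out 1 array brought these changes to as little as -2.03, -1.99 and -2.075. AT5G33370, a GDSL-type esterase gene, went from 89.2 ± 2.47 in mock to 6.85 ± 1.77 and AT2G33850 from 239.4 ± 45.5 to 31.5 ± 0.424. These genes fell by 2.78 ± 0.17 and 2.66 ± 0.15, each with a limma adjusted p of 7.19e-05. AT5G33370 also lay below the pseudocount early on average, and its change was -1.73 with the larger one. The largest rises among named genes were smaller. The chitinase family gene AT2G43620 rose from 106.9 ± 24.5 to 313.8 ± 60 (log2 change 1.50 ± 0.24, limma adjusted p = 0.00722). MSRB6 (AT4G04840), a methionine sulfoxide reductase, rose from 151 ± 41.7 to 404.4 ± 40.2 (limma adjusted p = 0.00224), SMZ (AT3G54990), an AP2-type repressor of flowering, by 1.34 ± 0.17, and the TRAF-like gene AT3G20370 by 1.34 ± 0.17. The malate transporter family gene AT1G68600 rose by 1.33 ± 0.22 and the class III peroxidase gene PRX71 (AT5G64120) by 1.28 ± 0.29.

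All 3 tested members of the auxin and cell expansion list fell early: IAA29 (AT4G32280), an auxin-response repressor, by 2.21 ± 0.20, and GH3.3 (AT2G23170), which conjugates auxin to amino acids, by 1.94 ± 0.32. Its shift passed camera with the preset correlation (adjusted p = 4.3e-07) but not with an estimated correlation (adjusted p = 0.169). All 3 tested members of the abscisic acid, cold and drought list, which holds 22 genes, fell as well. All 3 were COR genes, COR47 (AT1G20440) among them, so the other genes of that list are not covered. COR15B (AT2G42530) and COR15A (AT2G42540), which encode chloroplast proteins induced by cold, fell from 1959 ± 27.6 to 747 ± 150 and from 1183 ± 3.82 to 490.2 ± 113. The camera adjusted p of that list was 4.3e-07, and 0.169 with an estimated correlation. Of 3 heat shock list members, 2 fell (camera adjusted p = 0.00316, or 0.31 with an estimated correlation, and fry adjusted p = 0.278). GI (AT1G22770), a clock gene that is expressed towards evening, was the only tested member of the clock list and fell from 439.8 ± 24 to 131 ± 5.73, by 1.69 ± 0.12 (limma adjusted p = 0.00013). WRKY22 (AT4G01250), a transcription factor of pattern-triggered immunity, fell by 1.16 ± 0.17, and the other 4 tested members of that list did not pass. BCAT4 (AT3G19710), of methionine chain elongation for aliphatic glucosinolates, fell by 1.67 ± 0.25 (0.95 with the larger pseudocount), and PORB (AT4G27440), of chlorophyll synthesis, by 0.41 ± 0.10.

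Single members of other lists rose early. SWEET2 (AT3G14770), a sugar transporter, rose by 0.60 ± 0.14. It was the 1 called member among 5 of the sugar list, against 3 when adjusted over the list alone. That list's camera adjusted p was 0.0243, with an adjusted p of 0.276 under an estimated correlation, and its fry adjusted p was 0.104. Its median change was 0.364, or 0.298 without early replicate 2. UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, rose by 0.59 ± 0.14. None of the 3 tested salicylic acid genes passed. The one with the smallest p was SARD4 (AT5G52810), an enzyme of pipecolic acid synthesis, at -0.30 ± 0.19 (adjusted p = 0.444). None of the 10 photosynthesis genes passed (median log2 change -0.14, camera adjusted p = 0.159), and PSAN (AT5G64040) had the smallest p, at -0.25 ± 0.11. Without mock replicate 1 that list's median was -0.34 (camera adjusted p = 2.09e-05). Values that did not pass were also found for EIN3 (AT3G20770) at -0.07 ± 0.17, WRKY6 (AT1G62300) at -0.15 ± 0.25, the calnexin gene AT5G07340 at -0.46 ± 0.15 and the guard cell gene FMA (AT3G24140) at 0.46 ± 0.15.

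In total 669 of 13647 probe sets differed between early and mock at a limma adjusted p of 0.05, 285 higher and 384 lower. Of these, 294 carried 1 gene name. After median centring of each array 322 were higher and 299 lower, and among calls with a log2 change of at least 1, 48 were higher and 178 lower. Without early replicate 1 the split was 55 higher and 153 lower (208 in all), and without early replicate 2 it was 16 higher and 112 lower (128 in all). The calls of AT1G68600, PRX71, HSP17.6C, PORB, UGT78D2, SWEET2 and GH3.3 were lost without either early array and those of AT2G43620, AT2G29500, AT5G37670 and BCAT4 without early replicate 2, at limma adjusted p between 0.0538 and 0.313. Calls were also lost for UGT78D2 and SWEET2 without either mock array, for PRX71 and PORB without mock replicate 2 and for PORB without either late array (adjusted p between 0.0625 and 0.149). PORB was not called after median centring (adjusted p = 0.143) nor SWEET2 after quantile normalization (adjusted p = 0.0535). With no filter AT2G43620, AT1G68600, PRX71, HSP17.6C, PORB, UGT78D2, SWEET2 and GH3.3 were not called (adjusted p between 0.0511 and 0.141).

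The late comparison asked which host transcripts differed from mock while the interaction was maintained. The 3 largest rises among named genes were in genes that lay below the array medians in mock. AT1G13470, a gene of unknown function, went from 5.45 ± 0.354 to 254.4 ± 64.3 (SD, n = 2), a log2 change of 4.35 ± 0.23 (limma adjusted p = 1.31e-05). AT5G52760, of the heavy-metal-associated domain family, went from 2.95 ± 3.46 to 210.2 ± 141 (4.29 ± 0.41), and the lipid transfer protein family gene AT5G55450 from 27.7 ± 7.92 to 435.9 ± 76.7 (3.67 ± 0.25). The mock values of AT1G13470 and AT5G52760 lay below the pseudocount, which therefore sets the size and the order of these changes. With a pseudocount 4 times larger they were 3.03 for AT1G13470, 2.78 for AT5G52760 and 3.04 for AT5G55450. HSP17.6C rose by 3.31 ± 0.60, or by 2.05 without mock replicate 2, and the small heat shock protein gene AT1G52560 by 2.94 ± 0.49. GRX480 (AT1G28480), a glutaredoxin induced by salicylic acid, rose from 16.8 ± 3.75 to 209.2 ± 112, by 3.08 ± 0.32. The largest fall among named genes was in AT4G30650, of the low-temperature and salt-responsive membrane protein family, from 1354 ± 301 to 129.1 ± 27.6 (-3.32 ± 0.19, limma adjusted p = 1.49e-05). The change was -2.51 ± 0.20 for AT3G28310, -2.49 ± 0.23 for COR27 (AT5G42900), a cold-regulated gene under clock control, and -2.33 ± 0.19 for AT1G07050, a CCT-motif gene. It was -2.30 ± 0.16 for AT4G16146 and -2.29 ± 0.16 for AT4G34950, of the major facilitator transporters.

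Of 3 tested salicylic acid genes 2 rose late, GRX480 and SARD4 (0.95 ± 0.19, adjusted p = 0.00744). The list's camera adjusted p was 0.00209, and 0.195 with an estimated correlation, and it did not pass fry (adjusted p = 0.0564). Of 5 pattern-triggered immunity genes 3 rose, and 5 when adjusted over the list alone. PUB23 (AT2G35930), a ubiquitin ligase, rose from 40.05 ± 2.9 to 209.4 ± 130 (2.05 ± 0.33), the transcription factor gene WRKY53 (AT4G23810) by 1.73 ± 0.41 (1.0 without late replicate 2), and WRKY22, which had fallen early, by 0.60 ± 0.17. The camera adjusted p was 0.000209 for that list, and 0.195 with an estimated correlation, and it did not pass fry (adjusted p = 0.0728). All 3 heat shock list members rose, with ROF2 at 2.71 ± 0.42, at the same camera and fry values. Leaving out 1 array brought the change of ROF2 to as little as 1.83. Of 3 genes of protein folding in the endoplasmic reticulum 2 rose: BZIP60 (AT1G42990), a transcription factor of the unfolded protein response, by 0.62 ± 0.17, and ERDJ3B (AT3G62600) by 0.51. Without late replicate 2 these were 0.40 and 0.34. That list did not pass (camera adjusted p = 0.0543), but it passed after quantile normalization (camera adjusted p = 0.0442), with a replicate block (0.0378), without mock replicate 2 (0.0328) and without late replicate 1 (0.0337). PRX71 was again higher, by 1.12 ± 0.29, or by 0.59 without late replicate 2. PDF1.2 (AT5G44420), a defensin under jasmonate and ethylene control, had 18.8 ± 10.7 in mock and 33.1 ± 21.1 late, a difference of 0.59 ± 0.38 that did not pass (adjusted p = 0.36).

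In the abscisic acid, cold and drought list COR15B fell by 1.62 ± 0.14 and COR15A by 1.22 ± 0.14, with all 3 tested members lower (camera adjusted p = 0.000209; adjusted p = 0.195 with an estimated correlation). GI, the only tested clock list member, fell by 1.73 ± 0.12, to 127.2 ± 0.919. PORB was lower by 0.40 at an adjusted p of 0.0205. In the auxin list GH3.3 rose by 1.30 ± 0.32 (0.82 without mock replicate 1) and the other 2 members did not pass, nor did the list (camera adjusted p = 0.198, but 0.0328 without mock replicate 2). Of the 10 photosynthesis genes none passed, with a median of -0.01, and SBPASE (AT3G55800), of the Calvin cycle, had the smallest p (-0.27 ± 0.11, adjusted p = 0.132, and 0.0424 without mock replicate 1). That list's test moved with the mock array used: the median was -0.18 without mock replicate 1 (camera adjusted p = 0.0239) and 0.11 without mock replicate 2 (camera adjusted p = 0.0328). Of the 5 sugar list members none passed, with AT1G62660, a vacuolar invertase, at 0.36 ± 0.17. BCAT4 (0.80 ± 0.25), DFR (AT5G42800, 0.47 ± 0.25) and WRKY6 (0.67 ± 0.25) did not pass either, although WRKY6 passed without mock replicate 2 (adjusted p = 0.0457), and BCAT4 without mock replicate 2, without late replicate 2 and with the larger pseudocount (adjusted p between 0.0428 and 0.0465).

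In total 2039 probe sets differed between late and mock, 982 higher and 1057 lower, and 982 of the called probe sets carried 1 gene name. After median centring of each array 838 were higher and 1173 lower, whereas among calls with a log2 change of at least 1, 443 were higher and 167 lower. Without late replicate 2 the count was 1137, and PRX71, SARD4, PORB, GH3.3, WRKY53, BZIP60 and ERDJ3B were no longer called, at limma adjusted p between 0.057 and 0.191. Calls were also lost for GH3.3, BZIP60 and ERDJ3B without mock replicate 1, for PRX71 and WRKY53 without mock replicate 2, for PORB without late replicate 1 and for PORB, BZIP60 and ERDJ3B without either early array (adjusted p between 0.0556 and 0.154). BZIP60 and ERDJ3B did not pass after median centring of the arrays (limma adjusted p between 0.0736 and 0.0851), nor did PRX71, PORB, GH3.3, WRKY53, BZIP60 and ERDJ3B with no filter (between 0.0624 and 0.0938).

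**Figure D1:**
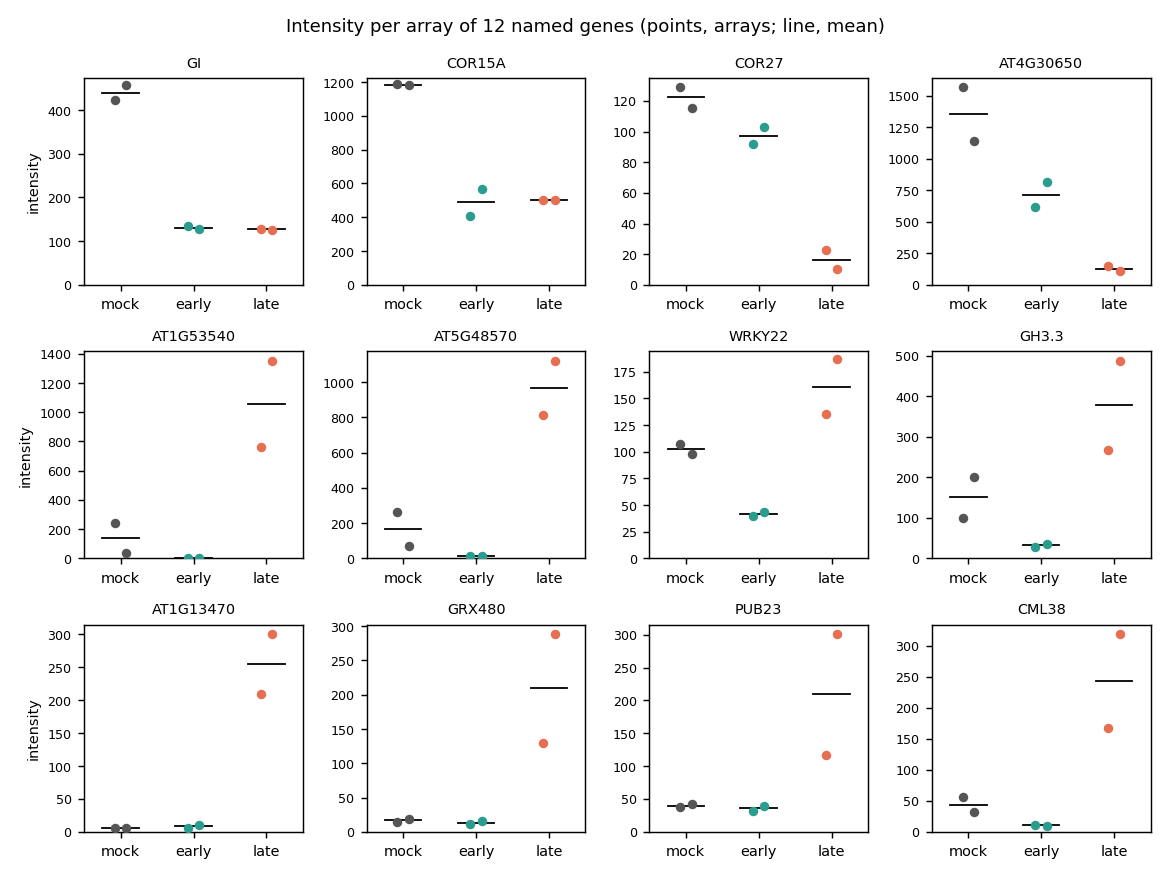
Intensity of 12 named genes on each of the 6 arrays, by group, with points for arrays and a line for the group mean, on a linear axis in array intensity units. GI and COR15A lay below mock at both stages, AT1G13470 and GRX480 averaged 254.4 and 209.2 late against 5.45 and 16.8 in mock, and HSP17.6C (AT1G53540) was at 3.6 early, 137.8 in mock and 1057 late on average.

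The late and early groups were compared directly to test whether the stages differed. Among named genes the largest differences were in heat shock genes, all higher late: HSP17.6C by 6.57 ± 0.60, ROF2 by 5.58 ± 0.42, AT2G29500 by 5.48 ± 0.43 and AT5G37670 by 5.22 ± 0.42, each with a limma adjusted p of at most 4.6e-05. The largest falls from early to late among named genes were AT1G07050 (-2.56 ± 0.19), AT4G30650 (-2.41 ± 0.19), AT3G20370 (-2.39 ± 0.17) and AT4G34950 (-2.27 ± 0.16). GRX480 was higher late by 3.32 ± 0.32, SARD4 by 1.26 ± 0.19, WRKY22 by 1.76 ± 0.17 and PUB23 from 35.6 ± 5.23 to 209.4 ± 130 (limma adjusted p = 0.00103). GH3.3 and IAA29 were higher late by 3.23 ± 0.32 and 1.85 ± 0.20, and BCAT4 by 2.47 ± 0.25. WRKY6, of senescence (0.82 ± 0.25), DFR, an enzyme of anthocyanin synthesis (0.93 ± 0.25), and the calnexin gene AT5G07340 (0.47 ± 0.15) were also higher late. With a pseudocount 4 times larger BCAT4 differed by 1.55, WRKY6 by 0.49 and DFR by 0.51. SWEET2 was lower late than early by 0.77, its relative SWEET11 (AT3G48740) by 0.46, HCT (AT5G48930), of lignin synthesis, by 0.59 and UGT78D2 by 0.55. GI (-0.04 ± 0.12), COR47 (AT1G20440, 0.25 ± 0.12), COR15A (0.06 ± 0.14) and COR15B (-0.23 ± 0.14) did not pass between the stages, except for COR47 after quantile normalization (limma adjusted p = 0.0403). None of the 10 photosynthesis genes passed. SBPASE had the smallest p, at -0.32 ± 0.11 (adjusted p = 0.0535), and passed after quantile normalization, after median centring, with the stricter filter, with a replicate block and without either mock array (adjusted p between 0.0111 and 0.0498). Values that did not pass were also -0.38 ± 0.15 for FMA, which passed after median centring (adjusted p = 0.0365), 0.06 for CHLM (AT4G25080) and 0.48 ± 0.38 for PDF1.2. PDF1.2b (AT2G26020) was higher late by 2.92 (limma adjusted p = 0.0197), or by 1.88 with 1 array left out. Its call was lost without either early array and without late replicate 2. With no filter PDF1.2b was not called either (limma adjusted p = 0.0789). In its list of defensin-like and RALF-like peptides, 2 of 14 tested members were higher late and 3 lower.

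Of the 8 preset lists tested, 4 differed between the stages by camera with the preset correlation. All 3 auxin genes, all 3 heat shock genes, 3 of 5 pattern-triggered immunity genes and 2 of 3 salicylic acid genes were higher late. Camera adjusted p was 0.000121 for the auxin and the heat shock lists, 0.00378 for pattern-triggered immunity and 0.0112 for salicylic acid. With an estimated correlation none of the 4 passed (adjusted p = 0.26 for each), while fry adjusted p values lay between 0.0359 and 0.0478. The minimum of 3 tested members for a list test was set after the members' changes had been seen. With a minimum of 5, the lists of pattern-triggered immunity, photosynthesis and sugar transport remain, and of these pattern-triggered immunity passed late against early (camera adjusted p = 0.00426; adjusted p = 0.445 with an estimated correlation).

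**Figure D2:**
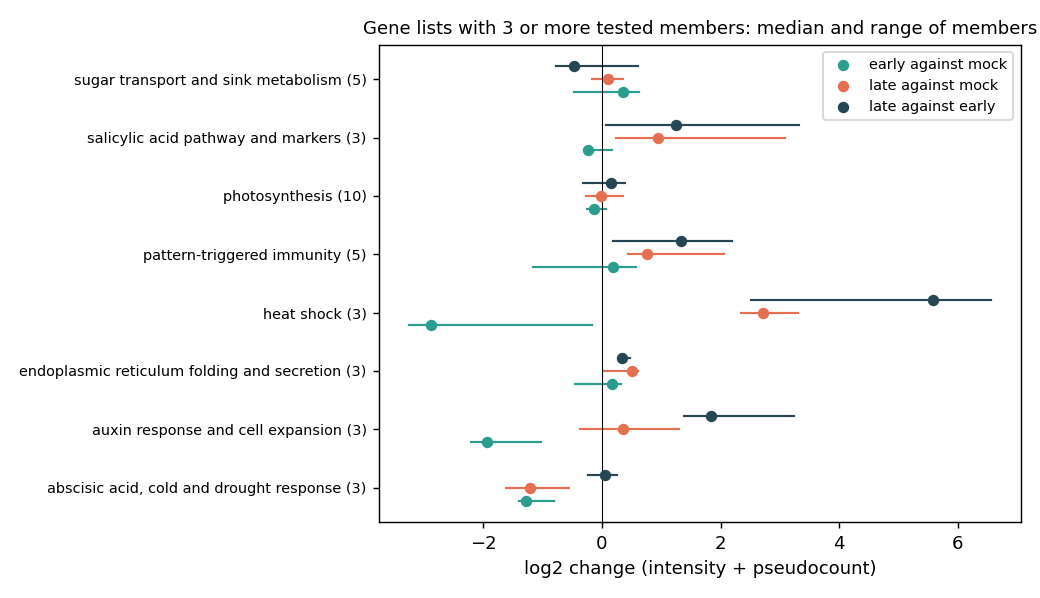
Median (point) and range (line) of the log2 changes of the members of the 8 gene lists with 3 or more tested members, for each comparison, with the number of tested members after each name. The heat shock list has a median of -2.87 early against mock and 2.71 late against mock, while the cold and drought list has -1.28 and -1.22.

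In total 3373 probe sets differed between late and early, 1454 higher late and 1919 lower. After each array was centred on its median, 1128 were higher and 2616 lower, as the centring moved the median change of all probe sets from -0.034 to -0.134. Among calls with a log2 change of at least 1, 613 were higher and 315 lower. Without early replicate 1 or 2 the count was 1621 or 1591, and WRKY6, UGT78D2, DFR, SWEET11 and AT5G07340 were then no longer called (limma adjusted p between 0.0501 and 0.324). Calls were also lost for AT5G07340 without either mock array or late replicate 1, for WRKY6 without either late array and for UGT78D2 without late replicate 2 (adjusted p between 0.0544 and 0.197). WRKY6 was not called after quantile normalization (adjusted p = 0.0928) nor AT5G07340 after median centring (adjusted p = 0.0915), and WRKY6, AT5G07340 and DFR were not called with no filter (adjusted p between 0.0678 and 0.0968).

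The overlap of the early and late changes against mock was then counted. In both comparisons 140 probe sets were called in the same direction, 68 higher and 72 lower, where independent lists would share 20.5 and 29.7. COR15A, COR15B, COR47, GI and PORB were lower at both stages, and PRX71 was higher at both. In opposite directions 170 were called, 115 lower early and higher late and 55 the other way, where independent lists would share 27.6 and 22.1. HSP17.6C, ROF2, GH3.3 and WRKY22 were among the first kind, and AT3G20370 and AT1G68600 among the second. Both comparisons used the same 2 mock arrays. A split of these arrays into 1 per stage was not made. In 100 simulations of unchanged groups sharing them, at most 1 probe set was called in the same direction and 0 in opposite directions. Those groups held 0.71 and 0.97 calls each on average, too few for a larger overlap. Part of the observed overlap in the same direction may therefore come from the shared mock arrays. Noise in the shared mock means moves both changes the same way. However, both comparisons also use the same spread estimate for each probe set, as they come from one fit. Probe sets with a low estimate are favoured in both, in any direction. The expectation for independent lists may therefore be too low for opposite calls as well, and the simulations held too few calls to show this. The log2 changes at the 2 stages had a correlation of -0.0876 across probe sets, which are not independent replicates, against a mean of 0.5 in the simulations. Their covariance was -0.0155, against 0.0162. Without early replicate 1 or 2, 31 or 21 shared calls in the same direction and 74 or 47 in opposite directions were found, and without mock replicate 1, 92 and 97.

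**Figure D3:**
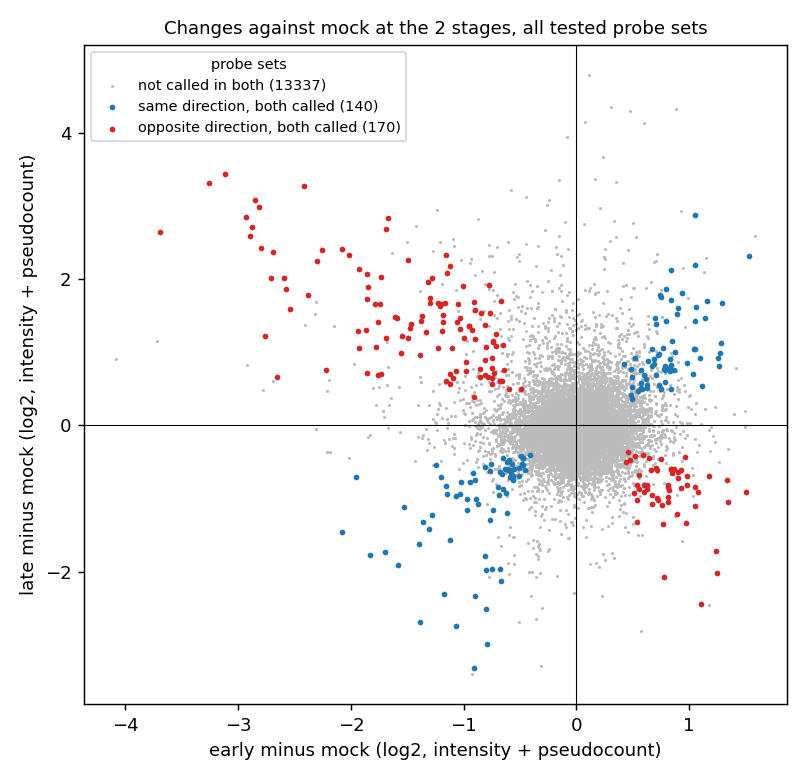
Log2 change of each of the 13647 tested probe sets early against mock (horizontal axis) and late against mock (vertical axis). Coloured points are called in both comparisons, 140 in the same direction and 170 in opposite directions.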

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

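The tests of an equal mix of RNA in mock and all tests on the control probe sets were chosen only after the result was seen, and the count of calls in opposite directions was added after seeing the data. In 170 probe sets the early and late changes against mock were called in opposite directions. Among the named genes the difference late minus early, tested in the same limma fit, was 6.57 for HSP17.6C (AT1G53540), 5.58 for ROF2 (AT5G48570), 5.48 for AT2G29500, 5.22 for AT5G37670, 3.33 for AT2G33850, 3.23 for GH3.3 and 1.76 for WRKY22. It was -2.08 for AT1G68600 and -2.39 for AT3G20370. By the camera test between the stages the median difference was 5.58 for the heat shock list, 1.85 for the auxin list, 1.33 for the pattern-triggered immunity list and 1.26 for the salicylic acid list, and none of these lists passed with an estimated correlation (adjusted p = 0.26).

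The pattern weighed first is the 115 probe sets that were lower than mock early and higher than mock late, heat shock genes among them. If mock were an equal mix of both collections and infection changed nothing, mock would lie midway between the stages on the linear scale. The median position on the way from early to late was 0.275 on mock replicate 1 and 0.221 on mock replicate 2 over these 115 probe sets. They were chosen because mock lay between the stages on the log2 scale, which itself favours a position below midway, so these positions do not decide. Over 17 heat shock and co-chaperone genes the median position was 0.263 and 0.0689. These were the genes called higher late than early among 18 tested, a choice that did not use mock. However, only 6 of the 18 had not been seen before the list was written. An unequal mix stays open. Scaling of the arrays alone is argued against by quantile normalization, which kept 109 of the 115, while median centring kept 94. A wound or handling response that differed between the collections remains possible, since 16 genes of rapid wound and touch responses had a median of 1.37 late minus early (log2) and -0.20 early minus mock. Many of these genes also respond to pathogens, so infection stage, which the design names, could account for the same values and stays open with collection time.

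The 25S rRNA control probe set, which no comparison used, was 1.67 times as high late as in mock, at 2267.2 and 2565.7 on the late arrays against 1472.3 and 1422 on the mock arrays. Both late arrays also lay above every mock and early array for 4 of 5 ubiquitin control probe sets (1.52, 1.38, 1.33 and 1.28 times mock) and 4 of 5 GAPDH ones (1.3, 1.25, 1.23 and 1.19 times mock), but for 0 of 6 actin ones, so the rise was not particular to rRNA. RNA degradation stays open, since the mean log2 ratio of 3' to 5' control signals was 1.04 and 1.15 on the late arrays and 1.11 and 1.28 on the mock arrays, which overlap. More labelling of RNA without a poly(A) tail stays open as well, with a median late minus mock of -0.12 over 67 plastid-encoded genes but 0.35 over 7 mitochondrion-encoded genes. RNA of the pathogen in the sample could raise a conserved rRNA signal without raising host mRNA, and the median of -0.043 over cytosolic ribosomal protein genes does not decide this. No probe set for a pathogen transcript was analysed here.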

How the results depend on the processing

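With 2 arrays per group, the counts of calls depended more on single arrays than on normalization, and quantile normalization gave 646, 2146 and 3396 for the 3 comparisons. For early against mock, 669 calls became 297 with no filter, 404 with no trend, 226 with a log2 change of at least 1 and 1127 at an adjusted p of 0.10, and leave-one-out counts ran from 128 to 837. For late against mock, 2039 calls became 610 with a change of at least 1, with 1137 to 1986 on leaving out one array. For late against early, 3373 became 928, with 1591 to 3661. Calls shared in the same direction fell from 140 to 50 with no filter and 66 with no trend (21 to 161 on leaving out one array). Calls in opposite directions, a count added after seeing the data, fell from 170 to 81 and 98 (47 to 199). No filter adds dim probe sets to the adjustment, and the other causes were not tested.

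Of 24 tests of preset lists, 12 passed camera. With fry 5 of these 12 did not pass, all of them against mock, and 1 further test passed. With an estimated correlation 0 passed, with the filter at the 60th percentile, which leaves fewer lists, 6 passed, and leaving out one array gave 11 to 15. With a list minimum of 5 tested members, an alternative chosen after seeing the data, 3 of 9 tests passed. The photosynthesis list late against mock (median -0.01) reversed to 0.11 without mock replicate 2 and was -0.18 without mock replicate 1, and the cause was not tested. Of 204 results on named genes, 59 lost their call without early replicate 2, 53 without early replicate 1 and 51 with no filter, and none reversed. The 204 include results not called in the main fit, which had no call to lose. The deviations of same-numbered arrays correlated weakly (-0.0513 for mock and early, 0.117 for mock and late, 0.115 for early and late). With 1 difference per group this does not decide whether the replicate number marks a shared experiment. With a replicate block the counts were 783, 2215 and 3559, with 169 and 194 shared calls in the same and in opposite directions.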

Other observations

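In this part, the tests of further salicylic-acid-induced genes and of malectin-like receptor kinase genes rest on the minimum of 3 tested members per list. That minimum was set after the members' changes had been seen. The list of clock genes was written after the leading genes were known. Of 7 calmodulin-like genes, calcium sensors, 6 rose late against mock (median 1.83, camera adjusted p = 3.28e-08; adjusted p = 0.222 with an estimated correlation). CML38 (AT1G76650) went from 43.95 ± 16.5 in mock to 10.45 ± 0.636 early and 242.4 ± 107 late (SD, n = 2), and AT3G47480 rose late by 2.44 ± 0.23, or by 1.53 with a pseudocount 4 times larger. The early call of CML38 was lost with that pseudocount, with no filter and without mock replicate 1 or either early array (limma adjusted p between 0.0737 and 0.131). Of 20 genes of the TIR-domain resistance family 5 rose (camera adjusted p = 3.44e-05, or 0.478 with an estimated correlation, and fry adjusted p = 0.0504, which did not pass). Among them AT3G04210 was at 2.19 ± 0.21 (1.37 with the larger pseudocount) and AT1G72900 went from 29.3 ± 7.92 to 149.2 ± 35.3. All 3 genes of a further list of salicylic-acid-induced genes rose, among them AT5G03350 by 2.41 ± 0.18 and RING1 (AT5G10380), a ubiquitin ligase gene, by 1.91 ± 0.23 (camera adjusted p = 2e-06; adjusted p = 0.478 with an estimated correlation). Of 10 cytochrome P450 genes 1 was called, CYP71B23 (AT3G26210), which rose by 2.51 ± 0.18, and the list did not pass (camera adjusted p = 0.248). Other added lists passed camera late against mock. Nuclear genes of plastid ribosomal proteins (adjusted p = 0.00535) and serine carboxypeptidase-like genes (0.0313) were lower. Malectin-like receptor kinase genes were higher (0.0255). With an estimated correlation none of these passed (camera adjusted p = 0.552, 0.543 and 0.478).

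Of 7 tubulin genes 5 fell late, with TUB9 (AT4G20890) at -1.11 ± 0.14 and TUB1 (AT1G75780) at -0.69 ± 0.15 (camera adjusted p = 0.00535; adjusted p = 0.478 with an estimated correlation). The call of TUB1 was lost without mock replicate 1 and without late replicate 2 (limma adjusted p = 0.0657 and 0.0677). Of 10 further nuclear photosynthesis and photorespiration genes 3 fell late, and the list did not pass (camera adjusted p = 0.111), except with no filter (0.0174) and without mock replicate 1 (0.0152). Its largest falls were in NdhN (AT5G58260) and NdhL (AT1G70760), subunits of the chloroplast NADH dehydrogenase-like complex, at -0.75 ± 0.14 and -0.68 ± 0.10. Of 23 UDP-glycosyltransferase genes 4 rose early, with UGT71B1 (AT3G21750) at 0.85 ± 0.14 and UGT78D1 (AT1G30530) at 0.78 ± 0.13. That list passed camera (adjusted p = 0.00335; adjusted p = 0.646 with an estimated correlation) but not fry (adjusted p = 0.145). The calls of UGT71B1 and UGT78D1 were lost without either early array (limma adjusted p between 0.0634 and 0.115). Among 111 cytosolic ribosomal protein genes the medians were -0.05 early and -0.04 late, and 2 were called at each stage.

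A last pattern weighed is the 72 probe sets called lower than mock at both stages, GI, COR15A and COR15B among them. The simulated unchanged groups that share the mock arrays held 0.71 and 0.97 calls on average, too few for an overlap of this size, so they do not decide how many of the 72 come from noise of the shared mock arrays. A different time of day of the mock collection could lower evening genes at both stages, but of 4 afternoon and evening genes, 3 of them seen before, 1 was called lower early (median -0.45) and 3 were called lower late (median -1.88). Over 6 dawn and morning clock genes, of which 1 had been seen before, the median size of the mean change against mock was 0.286 (log2), between the bounds set for and against this explanation. For GI, COR15A and COR15B both mock arrays lay above every other array. GI was at 422.8 and 456.8 in mock, 135 and 126.9 early, and 127.9 and 126.6 late. COR15A was at 1185.3 and 1179.9 in mock and at most at 570.2 elsewhere. COR15B was at 1939.9 and 1978.9 in mock and at most at 853.1 elsewhere. However, all 669 probe sets called early and all 2039 called late had arrays that did not overlap with mock. This separation therefore followed from the calls, and it does not set these genes apart from the rest of the 72. Noise of the shared mock arrays stays open for the 72 probe sets, as a split into 1 mock array per stage was not made. Time of day, plant age and infection cannot be told apart for the 72 probe sets, as the mock collection times are not given in the sources used here.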
